A study of Streptococcus pneumoniae D39 with 2 samples.

How the data were processed

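The arrays held probes for the genes of Streptococcus pneumoniae D39, an encapsulated laboratory strain of the pneumococcus. Per the labels, wild-type cells were grown in a chemically defined medium with 5 mM or 0 mM aspirin and harvested in mid-exponential growth. Total RNA was freed of DNA, copied into cDNA with aminoallyl nucleotides and coupled to Cy3 or Cy5, per the labels' protocols. Each of the 2 arrays received cDNA of both conditions. Aspirin cDNA carried Cy5 on array 1 and Cy3 on array 2, per the labels. The protocols mention several replicate cultures without saying which RNA went on which array. The limma p-values for single IDs therefore rest on the spread between 2 hybridisations, which may be technical, moderated by a spread pooled over IDs. No p-value here can be read as measuring the spread between cultures.

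The authors deposited, for each array, spot intensities on the linear scale of the scanner, with the local background median and background SD of both channels, before any normalisation (per the file headers). The percent of saturated pixels per spot was deposited in the same files. The scanner software's own ratio of channel means, another deposited column per the file headers, was read only to check which channel is which. Each array carried 5496 spots, 3 for each of 1832 IDs, and 63 IDs were further probes of a locus tag and were tested as IDs of their own. The median intensity was 1446.5 in Cy3 and 1520 in Cy5 on array 1, and 1747 and 1932 on array 2, against median backgrounds of 196, 165, 78 and 188 in that order. The number of arrays, 2, limits the precision.

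The authors also deposited a table with 1 linear ratio per ID and array. Set against the scanner intensities, both of its columns ran in the direction of aspirin over no aspirin (Pearson r across genes 0.997 and 0.996 with the unnormalised log2 ratio). The column medians were 0.968 and 0.834, so the columns were not centred. How spots were averaged and which background was used stays unknown. Of its IDs, 1769 matched the arrays and 1670 of these passed the filter on dim spots given below, so as an alternative the table was tested on 1670 IDs.

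Intensities were corrected with limma's normexp method (offset 50), and log2 ratios were normalised by loess over all spots of an array (whole-array loess). The 3 spots of an ID were averaged, and the sign of array 2 was turned so that every ratio is aspirin over no aspirin. An ID was kept where its mean intensity exceeded the local background by more than 2 background SDs on both arrays. That this was read as the median over the 3 spots was settled after the data were seen. The filter kept 1725 IDs and removed 107. Each ID was tested against a log2 ratio of 0 with limma (lmFit and eBayes, two-sided), which leaves 1 residual degree of freedom before moderation, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. The software that read the scans is not given in the sources used here.

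The groups, the tests, the gene lists, the rule for naming genes and all alternatives but 2 were fixed before the data were examined. The alternatives covered the background correction, the normalisation, the filter, the replicate spots, the authors' ratios, the variance prior, the threshold, the set test and single arrays. One of them was loess within each of the 48 blocks of spots (block-wise loess). Block-wise results are given beside those of whole-array loess because the counts differed widely. The 2 alternatives chosen after the data were seen were the authors' ratios centred on the median of each array, and a test of the lists that moved each list's pattern of genes along the chromosome.

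Gene lists were tested with limma's camera (two-sided, preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists) and, as alternatives, with an estimated correlation and with fry. Camera with an estimated correlation has only the 1 residual degree of freedom of the 2 arrays. With it 0 lists had an unadjusted p under 0.05, and even fatty acid synthesis had an unadjusted p of 0.184. That alternative could hardly call any list here, so its result does not count against a list. In the added test, the mean of a list was set against the means of the same pattern of genes at 1611 other places in the order of the 1670 plain locus tags, which keeps any likeness of neighbouring tags. It is called the position test, and its p-values were adjusted over the same lists. Its p-values, and those of camera with the preset correlation, rest mainly on the spread across genes. They do not measure the spread between arrays. On simulated data with like neighbours and no change (40 simulations of 20 lists), the position test called 0 of 800 lists and camera called 22. In 38 of those simulations the position test called the fatty acid synthesis list once its members had been lowered 2-fold. In simulations of independent genes with the spread of whole-array loess (200 of 1725 IDs changed, 20 simulations), limma called 44.4% of the 2-fold, 96.9% of the 4-fold and 99.2% of the 8-fold changes, and 0.564% of unchanged IDs. The changes were spread at random over these sizes, so the large ones eased the adjustment for the 2-fold ones. In the data ilvC, 3.18-fold lower, was not called by limma (adjusted p = 0.131). The shares therefore do not give the power in these data. Simulated spots with block offsets (1832 IDs, 5 simulations) gave calls for 0.208% of unchanged IDs after block-wise and 0.282% after whole-array loess, and 100% of the 2-fold changes were called after either. Those offsets were drawn separately for each block and array, so this simulation bears on false calls and not on the difference in calls between the 2 methods.

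The array files give locus tags of strains D39 and TIGR4 without gene symbols, and the reference gene table listed 0 of the array IDs. Symbols were therefore written down from general knowledge with both tags before the data were examined, and a symbol was used only where the files paired the same tags. Of 200 symbols with both tags, 192 were on the array and 175 were paired as written. Of 97 that the reference table also names, 94 lay within 25 kb of the place their neighbours gave and 3 (phtE, eno and pta) did not and were left out, which left 172 symbols. That check was revised once after the data were opened. In its first form, which kept misplaced symbols among the neighbours, 3 symbols were out of place as well, but adcAII stood in the place of pta, so which symbols it leaves out near these genes is uncertain. The remaining symbols rest on the tag pairs alone. Of 29 lists, 20 had at least 3 measured members. The other 9, among them capsule, ribosomal proteins, tRNA ligases, sugar phosphotransferase systems and transposases, were not analysed here.

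The genes named are the 12 largest rises and the 12 largest falls in mean log2 ratio among IDs past the threshold with 1 sign on both arrays. Where fewer passed, the places were filled with the IDs of largest mean log2 ratio that differed at least 1.5-fold with 1 sign on both arrays, given as values. In each list past its test, or with at least 2 members past the threshold, up to 4 members of largest absolute log2 ratio are named, and in other lists up to 2. IDs without a symbol are printed for 2 rises and 2 falls only. A few further list members are named where a count calls for it and were chosen after their values were seen.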

Results

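Transcript levels of wild-type S. pneumoniae D39 grown with 5 mM aspirin were compared with those of cells grown with 0 mM aspirin on 2 two-colour arrays with exchanged dyes. The comparison addressed which genes respond to aspirin, the acetylated salicylate drug. Values are mean log2 ratios of aspirin over no aspirin with the SD between the 2 arrays, after whole-array loess unless block-wise loess is named.

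Among the genes with a symbol, those of fatty acid, branched-chain amino acid and glutamine metabolism had lower ratios with aspirin. Chaperone and cell wall genes had higher ones. Of the 12 IDs ranked lowest and the 12 ranked highest among those that differed at least 1.5-fold with 1 sign on both arrays, 6 each had a symbol. The named decreases among them were those of accB (SPD_0386), a subunit of acetyl-CoA carboxylase, at -1.72 ± 0.63 (SD, n = 2), ilvC (SPD_0406) at -1.67 ± 0.09, ilvB (SPD_0404) at -1.58 ± 0.51, glnR (SPD_0447) at -1.53 ± 0.48, ilvN (SPD_0405) at -1.43 ± 0.13 and accA (SPD_0390) at -1.41 ± 0.04. The named increases were those of adhE (SPD_1834), an aldehyde and alcohol dehydrogenase, at 1.31 ± 0.05, grpE (SPD_0459) at 1.30 ± 0.14, dnaK (SPD_0460) at 1.23 ± 0.15, dltD (SPD_2002) at 1.04 ± 0.42, pflB (SPD_0420), pyruvate formate-lyase, at 0.95 ± 0.24 and clpL (SPD_0308) at 0.82 ± 0.22. The lowest ratio and the 2 highest ratios of this ranking belonged to IDs without a symbol. SPD_0275 had -1.88 ± 1.01, while SPD_0775 had 1.48 ± 0.21 and SPD_1932 had 1.36 ± 0.25. SPD_0274, also without a symbol, ranked 4th lowest at -1.60 ± 0.52. What the IDs without a symbol encode was not examined, so they may belong to lists that were not analysed here. With the authors' ratios SPD_0775 was at 0.78, SPD_1932 at 0.75 and pflB at 0.43.

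After whole-array loess, limma called 0 of 1725 IDs at the adjusted threshold (lowest adjusted p = 0.131, shared by 15 IDs), and 193 had an unadjusted p under 0.05 (75 higher and 118 lower), where 86 would be found by chance. After block-wise loess, limma called 411 IDs, of which 173 rose and 238 fell, and the 24 ranked IDs were all among them. All 411 had 1 sign on both arrays, 8 rose and 30 fell at least 2-fold, and the largest changes were a 2.91-fold rise and a 3.95-fold fall. The block-wise adjusted p was 4.37e-07 for accB, 6.46e-08 for ilvC, 5.56e-07 for glnR, 5.1e-07 for adhE, 1.28e-06 for grpE and 8.02e-06 for dnaK. Such small values rest mostly on the variance prior pooled over IDs. The prior had 17.5 degrees of freedom after block-wise and 4.65 after whole-array loess, against 1 residual degree of freedom. Limma called 109 IDs with the replicate spots kept separate, 27 without background correction, and, of the 1670 IDs tested from the authors' table, 151 (5 higher, 146 lower) from the authors' ratios and 13 (0 higher, 13 lower) from those ratios after centring. The count of 109 treats the spots of an ID on 1 array as partial replicates, although they share a hybridisation. For the uncentred authors' ratios the prior degrees of freedom were infinite, so every ID was tested with 1 shared SD of 0.359. The 151 calls therefore amount to a cut-off on the ratio. After centring the prior had 4.87 degrees of freedom.

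The genes of fatty acid synthesis fell as a list (13 of 13 fixed members measured, camera adjusted p = 9.25e-14, adjusted p = 0.538 with an estimated correlation). All 13 were lower on both arrays, with a mean of -1.11 and a median of -1.05. Their adjacent tags run from fabM (SPD_0378) to accA (SPD_0390) and cover the elongation enzymes, the acyl carrier protein gene acpP and the 4 subunits of acetyl-CoA carboxylase. accB was 3.29-fold lower, accA 2.66-fold, accC 2.54-fold and fabZ, a hydroxyacyl-ACP dehydratase, 2.45-fold. The smallest decrease was that of acpP at -0.79 ± 0.27. fabT, the repressor gene of the cluster, was at -0.97 ± 0.30 (-1.59 with the uncentred authors' ratios). By limma 0 of the 13 passed over all IDs and 13 passed adjusted over the list alone, and after block-wise loess all 13 fell over all IDs. The position test gave a permutation p of 0.00062, the smallest it can give (adjusted p = 0.00414).

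**Figure D1:**
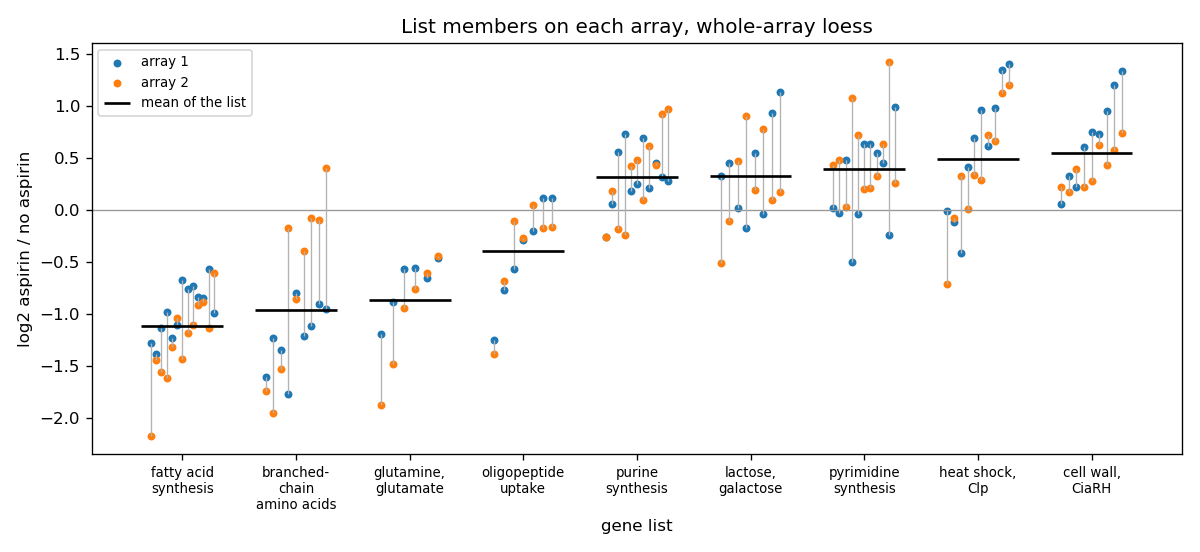
Log2 ratio of aspirin over no aspirin (vertical axis) for each measured member of the 9 gene lists past the camera threshold (horizontal axis), on array 1 (blue) and array 2 (orange), joined by a grey line, after whole-array loess. The black bar is the mean of a list, from -1.11 for fatty acid synthesis to 0.55 for the cell wall list.

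The branched-chain amino acid list also fell (9 members, mean -0.96, camera adjusted p = 1.17e-06, adjusted p = 0.538 with an estimated correlation), and 8 of its members were lower on both arrays. ilvB and ilvN, which encode acetolactate synthase, led the decrease together with ilvC, the ketol-acid reductoisomerase gene, which was 3.18-fold lower, and ilvN was 2.70-fold lower. The dimmest channel of ilvC was only 2.01 background SDs above background, so its ratio is uncertain despite its small SD. livJ, the binding protein gene of the branched-chain amino acid transporter, was at -0.97 ± 1.12, so its SD exceeded its mean. By limma 0 members passed over all IDs and 5 fell adjusted over the list alone. After block-wise loess 8 of the 9 fell over all IDs, livJ among them (-1.04 ± 0.35, adjusted p = 2.41e-05), and livM did not pass (-0.29 ± 0.26).

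The glutamine and glutamate list fell (6 members, mean -0.87, camera adjusted p = 2.26e-05, adjusted p = 0.538 with an estimated correlation), with 6 of 6 lower on both arrays. glnR, the regulator of glutamine metabolism, was 2.90-fold lower and glnA, glutamine synthetase, 2.27-fold lower. The glutamine transporter gene glnP was at -0.75 ± 0.26 and the glutamate dehydrogenase gene gdhA at -0.66 ± 0.14 (-1.23 with the uncentred authors' ratios). Limma called 0 members over all IDs and 5 adjusted over the list alone, and after block-wise loess 6 fell over all IDs. The position test gave an adjusted p of 0.00414 for this list and for the branched-chain list.

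Heat shock and Clp genes rose as a list (10 members, mean 0.49, median 0.57, camera adjusted p = 0.00159, adjusted p = 0.538 with an estimated correlation, adjusted p = 0.0186 by the position test). 7 of the 10 were higher on both arrays, while clpE (-0.04 ± 0.52), clpX (-0.09 ± 0.03) and htrA (-0.36 ± 0.50) were not. Of the measured Clp genes only clpL had a higher ratio, and clpC, clpP and ctsR of the fixed list have no value here. grpE and dnaK, partners in the DnaK chaperone system, were 2.47-fold and 2.35-fold higher, clpL, a Clp family ATPase gene, 1.77-fold and dnaJ 1.59-fold. The chaperonin gene groEL was at 0.51 ± 0.25 and groES at 0.21 ± 0.28. 0 members passed limma over all IDs, and 3 (grpE, dnaK and clpL) rose adjusted over the list alone. After block-wise loess, 6 rose over all IDs, including hrcA, dnaJ and groEL, while htrA, a surface protease gene, fell (-0.42 ± 0.12, adjusted p = 0.0213). With the uncentred authors' ratios the list mean was 0.30, groEL was at 0.31 and groES at 0.14.

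The cell wall list, made of the dlt operon for D-alanylation of teichoic acids and of the CiaRH and Lia regulatory systems, rose (9 members, mean 0.55, camera adjusted p = 0.000115, adjusted p = 0.538 with an estimated correlation). All 9 were higher on both arrays. dltD was 2.06-fold higher, ciaH, a sensor kinase gene, 1.85-fold and dltA 1.61-fold, and dltB was at 0.68 ± 0.08. Limma called 0 of them over all IDs and 0 adjusted over the list alone (lowest adjusted p = 0.0537). After block-wise loess dltD, dltB, dltA and ciaH rose over all IDs, and the 3 lia genes lay between 0.01 and 0.16. The position test gave an adjusted p of 0.0347 after whole-array and 0.0558 after block-wise loess. With the authors' ratios the list mean was 0.17 (0.32 after centring), still called by camera, and dltD was at 0.35 (0.50), ciaH at 0.16 (0.31), dltA at 0.28 (0.43) and dltB at 0.14 (0.29), none of them called.

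**Figure D2:**
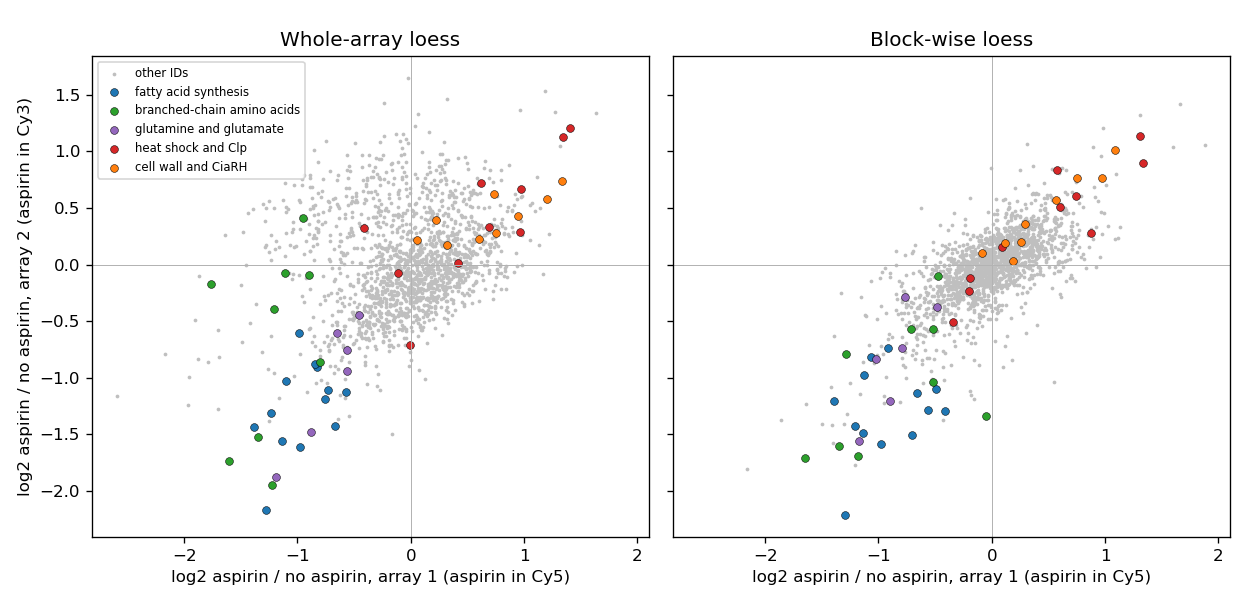
Log2 ratio of aspirin over no aspirin on array 1 (horizontal axis) against array 2 (vertical axis), 1 point per ID, after whole-array loess (left) and block-wise loess (right). Members of 5 gene lists are coloured, and Pearson r over 1725 IDs is 0.301 on the left and 0.72 on the right.

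The nucleotide synthesis lists had smaller shifts upward. The pyrimidine list rose (11 members, mean 0.40, camera adjusted p = 0.00159, adjusted p = 0.538 with an estimated correlation). Of its 11 members, 7 were higher on both arrays. By the position test its adjusted p was 0.0579 after whole-array and 0.0496 after block-wise loess. Its members of largest ratio were carB at 0.62 ± 0.51, pyrB at 0.59 ± 1.18, carA at 0.54 ± 0.13 and pyrDb at 0.43 ± 0.16. carA and carB encode carbamoyl phosphate synthase. After block-wise loess carA, carB, pyrDb, pyrK and pyrE rose over all IDs. The purine list rose by camera (11 members, mean 0.31, adjusted p = 0.00981), but not by the position test (adjusted p = 0.233) or with an estimated correlation, which could hardly call any list (adjusted p = 0.538). Of the 11 purine members, 8 were higher on both arrays. The purine list had purM at 0.63 ± 0.49, purF at 0.62 ± 0.43, purK at 0.44 ± 0.01 and purD at 0.41 ± 0.28, and 3 members rose after block-wise loess. In both lists 0 members passed limma over all IDs or adjusted over the list alone. With the uncentred authors' ratios the means were 0.21 for the pyrimidine and 0.20 for the purine list, and carB was at 0.17 and carA at 0.21.

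The lactose and galactose list was also called higher by camera (8 members, mean 0.33, adjusted p = 0.0351), but not by the position test (adjusted p = 0.307) or with an estimated correlation, which could hardly call any list (adjusted p = 0.538). The list had lacE at 0.65 ± 0.68, lacG at 0.52 ± 0.59, lacC at 0.37 ± 0.58 and galK at 0.37 ± 0.25. Only 4 of its 8 members were higher on both arrays. Several of its ratios are uncertain, because the dimmest channels of lacT (1.8), lacF (2.19), galK (2.45) and lacC (2.69) lay few background SDs above background. The oligopeptide uptake list was called lower (7 members, mean -0.40, adjusted p = 0.0331), but not by the position test (adjusted p = 0.207), after block-wise loess (adjusted p = 0.128) or with an estimated correlation, with the same limit (adjusted p = 0.538). Of its 7 members, 4 were lower on both arrays. After whole-array loess the shift of this list came mostly from aliA, an oligopeptide-binding protein gene, at -1.31 ± 0.09 and from amiA, another such gene, at -0.72 ± 0.06, while amiF was at -0.33 ± 0.33 (-0.91 with the uncentred authors' ratios) and aliB at -0.28 ± 0.01. Adjusted over the list alone, limma called 1 gene of the oligopeptide list (aliA) and 0 of the lactose list, and over all IDs 0 in either. After block-wise loess lacE rose and aliA, amiA and amiF fell over all IDs. The oligopeptide mean was -0.72 with median centring and -0.93 with the authors' ratios (-0.78 after centring), and the lactose mean was 0.20 with the uncentred authors' ratios.

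The other 11 lists did not pass camera, and 0 of their members passed limma over all IDs after whole-array loess. In the glycolysis and fermentation list (12 members, adjusted p = 0.699), adhE and pflB rose adjusted over the list alone, whereas ldh, lactate dehydrogenase, was at 0.04 ± 0.20 (-0.18 with median centring, -0.41 with the authors' ratios) and the phosphoglycerate kinase gene pgk at -0.66 ± 0.12. The mean of that list was 0.10, its median was -0.01, and its mean turned to -0.11 with median centring and to -0.34 with the authors' ratios. In the zinc, manganese and copper list (14 members, adjusted p = 0.382) the zinc exporter gene czcD was at 0.78 ± 0.27 (0.36 with the uncentred authors' ratios) and psaA, the manganese-binding protein gene, at -0.57 ± 0.13. Among surface and virulence genes (9 members, adjusted p = 0.382), ply, the pneumolysin gene, was at -0.80 ± 0.0012 and nanB at 0.53 ± 0.39. The nanB ratio is uncertain, because its dimmest channel was only 1.81 background SDs above background. After block-wise loess czcD rose over all IDs (limma adjusted p = 0.000379), as did adhE, pflB and, with that limit, nanB (adjusted p = 0.042), while psaA (adjusted p = 0.00382), ply (adjusted p = 2.1e-05) and pgk (adjusted p = 0.0124) fell.

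Late competence genes (9 members, adjusted p = 0.121) included comGA at 0.81 ± 0.38 and cbpD at 0.44 ± 0.75, and early competence genes (6 members, adjusted p = 0.761) comB at 0.49 ± 0.35 and comA at 0.34 ± 0.48. Of the iron uptake genes (8 members, adjusted p = 0.699), piuD was at -0.49 ± 0.23 and piuA at -0.45 ± 0.28, and both fell after block-wise loess. piuA was at -0.68 with median centring and at -0.91 with the uncentred authors' ratios, where limma called it with 1 SD shared by all IDs. In the ATP synthase list (8 members, adjusted p = 0.382) atpE was at -0.63 ± 0.48 and atpF at 0.32 ± 0.06, and the sign of atpF turned with median centring (-0.08) and with the authors' ratios (-0.36). The oxidative stress list (6 members, adjusted p = 0.991) had tpxD at -0.28 ± 0.04 and dpr at 0.27 ± 0.18, and dpr turned to -0.05 with median centring. The arginine list (3 of 7 fixed members measured, adjusted p = 0.166) had arcB at 0.53 ± 0.25 and arcC at 0.25 ± 0.38. The maltose list (3 of 12 fixed members measured, adjusted p = 0.111) had malX at 0.47 ± 0.47 and malC at 0.38 ± 0.42. Its other fixed members were not matched to tags, so this result covers only part of the list. SPD_1932 (1.36 ± 0.25), in the same block-wise run of 3 tags as malX, had no symbol and was not tested with the list. The riboflavin list (3 of 8 fixed members measured, adjusted p = 0.308) had ribD at 0.29 ± 0.11 and ribB at 0.26 ± 0.04. Camera called the riboflavin list higher with background subtraction (adjusted p = 0.0448) and median centring (adjusted p = 0.0358), and the ATP synthase and oxidative stress lists lower with the centred authors' ratios (adjusted p = 0.0389 for both). After block-wise loess comGA, cbpD, comB and malX rose and atpE fell over all IDs by limma. Apart from piuD and piuA, no other member named from these 8 lists passed.

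Without any test, 6 IDs were at least 2-fold higher and 15 at least 2-fold lower on both arrays, against a mean of 1.66 and a maximum of 9 in 10000 shuffles of the genes of array 2. adhE, grpE and dnaK were among the higher, and accB, accA, accC, accD, fabD, ilvB, ilvC, ilvN, glnR and aliA among the lower. Median centring gave 4 higher and 30 lower, the authors' ratios 0 and 40, and those ratios after centring 2 and 29. At least 2-fold differences on a single array numbered 17 higher and 71 lower on array 1, and 25 and 35 on array 2.

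The same sign on both arrays was found for 982 IDs (56.9%). Across genes, which are not independent replicates, the ratios of the 2 arrays correlated with r = 0.301 (95% bootstrap interval 0.248 to 0.352) and rho = 0.262 after whole-array loess, and with r = 0.72 and rho = 0.687 after block-wise loess. The SD over IDs of the mean ratio was 0.391 and that of the dye component (the difference between the arrays divided by 2) was 0.287. The median ratio of a block of spots had an SD over the 48 blocks of 0.313 on array 1 and 0.334 on array 2, and the medians of the 2 arrays were inversely related (r = -0.541).

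**Figure D3:**
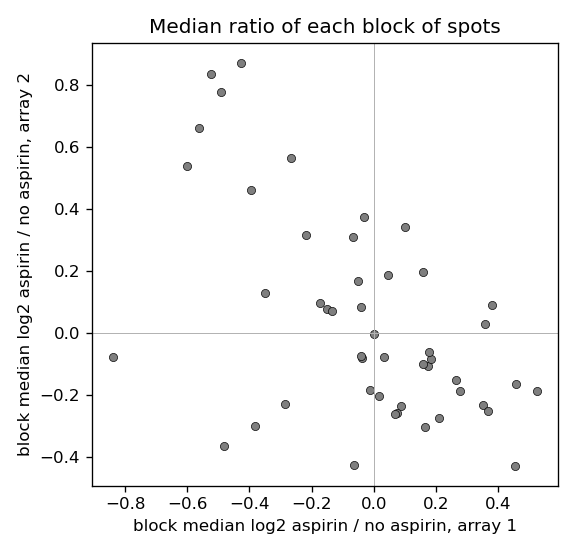
Median log2 ratio of aspirin over no aspirin of each of the 48 blocks of spots on array 1 (horizontal axis) and array 2 (vertical axis), after whole-array loess, 1 point per block. Blocks high on array 1 tend to be low on array 2 (r = -0.541).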

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

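Of the alternatives described here, the centred authors' ratios and the position test were chosen after the data were seen. The number of IDs that limma called, 0 after whole-array loess (193 at an unadjusted p under 0.05), depended on the setting. It was 411 after block-wise loess (173 higher, 238 lower), 151 with the authors' ratios (5 higher, 146 lower; median of all genes -0.139), 109 with separate replicate spots (37 higher, 72 lower; consensus correlation 0.384), 27 without background correction (7 higher, 20 lower), 13 with the centred authors' ratios (0 higher, 13 lower) and 8 at an unadjusted p under 0.001 with at least 2-fold change (2 higher, 6 lower). It stayed 0 with background subtraction, median centring, Aquantile, no filter on dim spots, and an intensity trend with a robust prior. Aquantile changes the intensities and leaves the log2 ratios as they are, so its 0 repeats the main result. The 109 calls treat spots of 1 hybridisation as partly independent. The 151 calls use 1 SD shared by all IDs. The count of IDs at least 2-fold changed on both arrays, 21, was 14 without background correction, 17 with background subtraction, 34 with median centring, 40 with the authors' ratios, and 60 to 88 on a single array. The correlation between the arrays, 0.301, was 0.72 after block-wise loess, 0.48 with the authors' ratios (1670 IDs), 0.399 with median centring and 0.288 to 0.332 in the other settings where it was computed. Camera called 9 lists and 8 to 11 over the normalisations, but 0 with an estimated correlation, 3 by fry (oligopeptide uptake, purine and riboflavin), 3 by its mixed test (branched-chain amino acids, oligopeptide uptake and oxidative stress) and 5 by the position test. The 0 comes from a test with 1 residual degree of freedom, which could hardly call any list. Fatty acid, branched-chain, glutamine, cell wall, heat shock, purine and pyrimidine lists passed camera in all 10 normalisation and variance settings, oligopeptide uptake in 9, lactose in 6, riboflavin in 2 (higher), oxidative stress in 1 (lower) and ATP synthase in 1 (lower). The 10 include the main setting and Aquantile, which has the same ratios. Of 76 named IDs (62 by the rule and 14 further list members), 73 kept their direction in every alternative with both arrays, and 7 (arcC, comA, cbpD, lacC, pyrB, livM and ldh) had the other sign on 1 array, as had 3 lists, none of them called. The exceptions with both arrays, for which the cause was not tested, were atpF (-0.077 with median centring, -0.36 and -0.21 with the authors' ratios before and after centring), dpr (-0.05005, -0.32 and -0.17) and ldh (-0.18, -0.41 and -0.26). The lists that turned against the other genes were ATP synthase (-0.20, -0.43 and -0.28, the last called lower by camera with an adjusted p of 0.0389), glycolysis (-0.11, -0.34 and -0.19) and, with the authors' ratios before and after centring, surface genes (-0.20 and -0.0495). The means of the early competence (-0.08) and zinc lists (-0.07) also fell below 0 with the uncentred authors' ratios. Spots flagged by the scanner software could not be varied, since 0 were flagged. The filter on signal over background removed 107 IDs, which have no value here. Each ratio pairs the conditions within an array, so every test of ratios was a paired one.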

Other observations

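The tests of surface unevenness, of dye bias, of array position for the fatty acid genes and the count of runs were chosen after the result was seen, and the other tests were set out before.

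Runs of consecutive locus tags that changed 1 way after block-wise loess were more frequent than chance placement gives. There were 28 runs of at least 3 tags (13 higher, 15 lower, 129 genes), against a mean of 4.02 and a maximum of 12 in 1000 shuffles of the calls over the tags. Of the 28 runs, 11 held a gene with a symbol. The shuffles removed the likeness of neighbouring tags given below, part of which was also in the dye component. An excess of runs follows from that likeness and is no separate support. The fatty acid cluster formed a run of 13 tags (mean -1.10), ilvB, ilvN and ilvC began a run of 5 (mean -1.50), and pgk, glnR and glnA lay in another run of 5 (mean -0.76). hrcA, grpE, dnaK and dnaJ formed a run of 4 (mean 0.87), and ply began a run of 4 (mean -0.91). czcD lay in a run of 6 (mean 0.62) and malX in a run of 3 (mean 1.06). The longest run, 21 tags that fell by a mean of 0.62, held no gene with a symbol. Genes of the lists defined by product name, such as ribosomal proteins, were not matched to tags. Such genes may therefore lie in this run or in others. The genes named for these runs were chosen after their values were seen.

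The rise from 0 to 411 called IDs with block-wise loess may come from uneven signal across the array surface that the dye swap turned into spread. The 3 spots of an ID lie in 3 different blocks, and block-wise loess lowered their median SD by 45.9%, from 0.246 to 0.136 on array 1 and from 0.221 to 0.117 on array 2. Differences shared by the genes of a block, which block-wise loess would remove in error, should have appeared with 1 sign on both arrays. Block medians instead correlated with r = -0.541 (permutation p = 2e-04), so such differences did not dominate them. A smaller shared part beneath the unevenness would not show in this r and stays open. Loess over blocks filled at random called 0 to 73 IDs in 20 draws, fewer than the true blocks. Those draws left the unevenness between blocks in the ratios (highest r between the arrays 0.303), which holds calls down. They therefore cannot tell how many of the 411 calls come from the flexibility of the fit.

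The decrease of the fatty acid genes was not accounted for by the technical explanations tested. Their median aspirin effect was 5.57 times their median dye effect, and their median lay 1.04 below that of intensity-matched random lists (difference -1.04), under all of 10000 such lists. The mean of 13 adjacent genes relative to all genes reached -0.666 at the lowest of 1611 other places, against -1.11 for the cluster. Whether aspirin acts on these genes directly or through other changes was not tested. Other differences between the cultures, such as growth at harvest, remain open, since no array of 2 untreated cultures was analysed here.

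Neighbouring tags had similar ratios over the whole chromosome, and whether this comes from shared transcripts was left open by the test. The correlation between adjacent tags (1429 pairs) was 0.584 in the mean ratio and 0.566 in the dye component (the difference between arrays divided by 2) after whole-array loess, and 0.567 (permutation p = 1e-04, the smallest that 10000 permutations can give) and 0.388 after block-wise loess. The bounds set beforehand, an excess over 0.2 for shared transcripts and under 0.05 against them, named no loess, and the excess was 0.0181 after whole-array loess, below the lower bound, and 0.179 after block-wise loess, between the bounds, so shared transcripts and a technical likeness of neighbours cannot be told apart. The whole-array value does not exclude shared transcripts, because the dye component then held a likeness within blocks (0.684 for IDs over 50 tags apart in 1 block, against 0.0424 in the mean ratio). After block-wise loess, adjacent tags at the same position of their blocks correlated at 0.629 in the mean ratio and 0.55 in the dye component (a split examined after the result was seen), those at other positions at 0.488 and 0.186, and IDs over 50 tags apart at the same position (4908 pairs) at 0.165 in the dye component and at -0.0324 in the mean ratio, so print position alone did not give the likeness in the mean ratio.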
